A study of Homo sapiens with 12 samples.

How the data were processed

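RNA was isolated from frozen tumour and normal colon tissue and sequenced on an Illumina HiSeq, per the labels' protocols. The protocol text names an exome capture kit, which enriches coding transcripts with probes, and in a second passage a stranded mRNA kit, and the sample descriptions name the capture method. Which kit made each library is otherwise not given in the sources used here. Groups were taken from the tissue labels: 7 tumour and 5 adjacent normal libraries, 1 per tissue piece. The patient label pairs the samples, since 5 of the 7 patients gave both tissues.

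Each sample's file holds deposited raw counts of read pairs per gene in 3 columns, without strand and for each strand. Reads were checked with FastQC and aligned with STAR 2.4.2a, and DESeq2 and DESeq were used, on build hg19 or GRCh37, per the submitters' processing notes, which give no order or settings. The gene annotation is not given in the sources used here. The authors' deposited table of tumour against normal holds log2 fold changes with standard errors, a test score, p-values with adjusted p-values, a mean signal and a normalized signal per library. The normalized signal equals the deposited unstranded counts divided by 1 factor per library for 100% of genes in each library. Genes marked by the authors as up (2094) or down (2409) in the deposited table had absolute log2 fold changes of at least 0.585. No column of per-sample values was left unused for want of a label (0 columns).

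The counts in column 4 were used, by a rule set beforehand: reverse-strand totals had to be at least 2 times the forward-strand totals in every library, and the lowest ratio was 25.7. Strand-specific counting separates most antisense overlaps, but near-identical gene copies cannot be told apart. The counts hold 26334 genes, of which 25172 symbols matched the reference gene table (assembly GRCh38.p14), used for names and chromosome arms only. XIST, TSIX and Y-linked genes were left out (108 genes), and genes with a common germline deletion were never named. Read pairs that fell in no gene made up 7.09% ± 2.15 in tumours (SD, n = 7) and 3.88% ± 1.17 in adjacent normal colon (SD, n = 5) of the pairs mapped to 1 place, ambiguous pairs 1.69% and 1.10%, and multimapped pairs 12.4% and 16.4% of all pairs. These stayed out of library sizes and tests. The 12 libraries held 11.7 to 33.9 M (mega) counts in genes, so a gene at 1 CPM rests on about 10 counts or more per library. Intervals and floors cover counting error only, since read pairs without molecular identifiers are not independent molecules. No 2 libraries of a group agreed within sampling noise, the lowest chi-square per gene being 96.7.

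Differential expression used edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, the quasi-likelihood F-test on group over all 12 libraries, and Benjamini-Hochberg adjustment, with genes called below 0.05. In all 14862 genes passed the filter, the common biological coefficient of variation was 0.646, and 5436 genes had an unadjusted p below 0.05. Fold changes are those of edgeR at its default prior count, while log2 CPM values use a prior count of 2. SE is the unshrunk log2 fold change over the root of the F statistic. The median log2 fold change of all genes was 0.0353, and other scalings moved it by −0.0642 and 0.0425. Fixed before the data were examined were 31 gene lists of 421 genes with no gene in 2 lists, covering pathways, chromatin complexes and markers of the cell types the tissue could hold, and 39 autosomal arms with at least 20 tested genes. Lists and arms were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated one. Library measures were compared with exact two-sided permutation tests over all 792 splits. The permutation tests here treat all libraries as exchangeable and ignore the pairing by patient.

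Named genes followed a rule fixed beforehand. It took the 12 largest rises and 12 largest falls among called genes with a mean of at least 1 CPM and the same direction in all 5 pairs. From each list it took the 2 smallest adjusted p and the 2 largest fold changes among called members, or the 2 most abundant where none was called, and it added a fixed set of genes. It gave 110 genes, of which 91 were called, and 58 of these stayed called in every fit without a single library in which they were tested. Of the 58, ATG9B, BEST4 and MYOT were each tested in 11 of the 12 such fits, and the others in all 12. Genes of the doubted libraries were picked for mention after their values were seen.

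The patient pairing was checked on deviations from the group means: the same-patient correlations ran from −0.117 to 0.369, with a mean of 0.162 against −0.0208 for other pairs, and 3 of 5 normal libraries correlated best with their own tumour. The pairing itself comes from the patient label. Alternatives were DESeq2 size factors and upper quartile scaling, no filter and a stricter one (1 CPM in at least 5 libraries), DESeq2 1.42.0, limma-voom, robust dispersion, unstranded counts, tumours with a matched normal, the patient as a block and as a random effect (consensus correlation 0.128), leaving out each library, other distances, an estimated correlation, and an adjusted p of 0.01. Removing the 2 doubted libraries was added after seeing the data. On simulated counts for the tumour against adjacent normal comparison, with 14629 genes tested, edgeR recovered 47 of 100 genes changed 4-fold and 3 of 100 changed 2-fold, with 2 false calls, or 3.85% of its calls. DESeq2 recovered 72 and 23, with 43 false calls, or 31.2%, and limma-voom 45 and 4, with 2. Only the genes changed 4-fold or 2-fold differed in the simulation, a much smaller share than the 21.8% of tested genes called in the data. The adjusted threshold depends on that share, so these recovery and false call rates cannot be carried over to the data.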

Results

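Gene expression was measured by RNA-seq in frozen human tissue, in 7 colorectal tumours and 5 pieces of adjacent normal colon from 7 patients, of whom 5 gave both tissues. The series belongs to a study of the epigenomic landscape of colorectal cancer, and its expression data set tumour against normal colon. Each file held 1 library. Tumour libraries held 11.7 to 28 M (mega) read pairs counted in genes, with a mean of 19.7 ± 6.29 M (SD, n = 7), and adjacent normal libraries 20.4 to 33.9 M, with a mean of 27.2 ± 4.98 M (SD, n = 5). The difference in depth did not pass an exact two-sided permutation test (p = 0.0568, Benjamini-Hochberg adjusted p = 0.102 over 9 library measures). Of the 9, 4 passed: tumours held more pairs in no gene (7.09% against 3.88%, adjusted p = 0.0341) and ambiguous pairs (1.69% against 1.10%, adjusted p = 0.0284), and less on the opposite strand (2.04% against 2.68%, adjusted p = 0.0284) and in the 10 most abundant genes (14.4% against 21.9%, adjusted p = 0.0341). Values below are library-scaled counts (CPM, per M counts) as mean ± SD with n = 7 tumours and n = 5 adjacent normal libraries, and log2 fold changes of tumour over adjacent normal with their approximate standard error (SE). Adjusted p-values of genes come from edgeR's quasi-likelihood test.

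Tumours differed from adjacent normal colon in 3240 of 14862 genes tested, or 21.8%, with 1590 higher and 1650 lower in tumour. Of these, 2512 changed at least 2-fold, 1119 upward and 1393 downward. The tumour and normal libraries moved the same way in all 5 patient pairs for 2624 of the called genes, or 81.0%. With the patient as a block, 1558 genes passed, 663 higher and 895 lower, and 1427 of them were among the 3240. Leaving out single libraries gave 2080 to 3837 genes. The 2 lowest counts, 2082 and 2080, came without adjacent normal replicate 1 and without adjacent normal replicate 2.

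In 1 adjacent normal library, genes of skeletal muscle took 17.4% of the counts, against 0.00539% to 0.0113% in the other adjacent normal libraries. That library held 2.82 CPM of EPCAM, an adhesion protein of all gut epithelium, against 932 to 2061 CPM in the other adjacent normal libraries. In 1 tumour library, genes of stratified squamous epithelium took 21.1% of the counts, against at most 0.0187% in the other tumours. Both carry the same patient label and so form 1 of the 5 pairs. Both stayed in the comparison and in the counts over pairs. Without both, a choice made after seeing the data, 3310 genes passed, 1461 higher and 1849 lower, and 2569 of them were among the 3240. Smooth muscle genes took 6.49% ± 5.87 of the counts in adjacent normal colon (SD, n = 5) and 0.0980% ± 0.0667 in tumours (SD, n = 7), a difference that passed an exact two-sided permutation test (p = 0.00126).

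**Figure D1:**
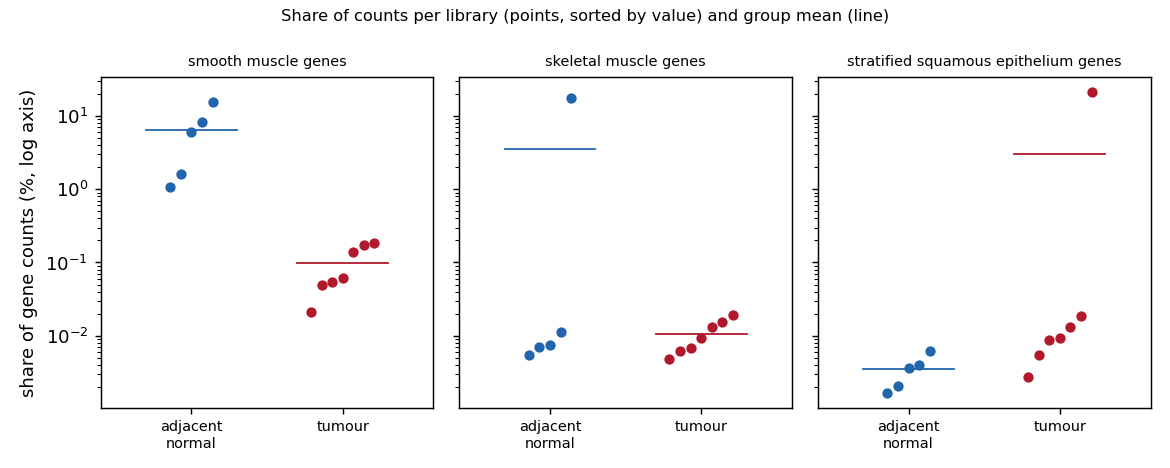
Share of gene counts (%, log axis) taken by smooth muscle genes, skeletal muscle genes and stratified squamous epithelium genes in each adjacent normal library (blue) and each tumour library (red), sorted by value within a group, with a line at the group mean. The adjacent normal libraries span 1.09% to 15.5% for smooth muscle genes and the tumours 0.0208% to 0.185%, while 1 adjacent normal library stands at 17.4% for skeletal muscle genes and 1 tumour at 21.1% for squamous genes.

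Among genes that rose in all 5 pairs, the 12 largest increases included genes of proteases, keratins and tight junctions. MMP7, a matrix-degrading protease, rose from 0.0229 ± 0.0513 to 7.37 ± 6.06 CPM, a log2 fold change of 8.27 ± 1.34 (SE, adjusted p = 0.00206). DPEP1, a membrane dipeptidase, rose from 0.512 ± 0.242 to 141 ± 97.9 CPM (log2 fold change 8.08 ± 1.03 SE, adjusted p = 0.00132). KRT23, a keratin, rose by a log2 fold change of 7.74 ± 1.19 SE, CLDN2, a pore-forming tight junction protein, by 7.53 ± 1.70 SE, KLK6, a secreted protease, by 9.14 ± 1.97 SE, and ATG9B, an autophagy protein, by 7.48 ± 1.59 SE. CA9, a carbonic anhydrase induced by low oxygen, rose from 0.171 ± 0.197 to 67.2 ± 96.2 CPM. The squamous-rich tumour library carried much of the rest. SPRR2D, S100A7, DSC3, KRT17 and S100A2, genes of skin and other squamous epithelia, had log2 fold changes of 11.71, 11.11, 9.06, 8.67 and 7.70, and 5.34, 5.55, 5.06, 2.64 and 2.95 without both doubted libraries. S100A7, KRT17 and S100A2 then no longer passed, with adjusted p of 0.0652, 0.0514 and 0.0569. With the patient as a block, S100A7, DSC3, KRT17 and S100A2 did not pass either, with adjusted p of 0.144, 0.102, 0.109 and 0.129. All 5 lost their calls without some single adjacent normal libraries, with adjusted p up to 0.0542 for SPRR2D, 0.0748 for S100A7, 0.0516 for DSC3, 0.0828 for KRT17 and 0.0765 for S100A2. By limma-voom none of these 5 passed (adjusted p from 0.208), nor did DPEP1, KRT23, CLDN2, KLK6 and CA9 (adjusted p = 0.0531, 0.107, 0.307, 0.174 and 0.268).

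Among genes that fell in all 5 pairs, the 12 largest decreases included genes of muscle and of fat cells. LDB3, a Z-disc protein, and SMYD1, a muscle methyltransferase, had log2 fold changes of −9.41 ± 1.35 SE and −9.22 ± 1.18 SE. FABP4 and PLIN4, genes of fat cells, had log2 fold changes of −8.60 ± 1.64 SE and −8.92 ± 1.5 SE. Without the skeletal-muscle-rich library alone, LDB3, SMYD1, FABP4 and PLIN4 had log2 fold changes of −6.84, −8.21, −5.28 and −6.99. PPP1R1A, a phosphatase inhibitor, had no counts in any tumour, and its 18 ± 32.3 CPM in adjacent normal colon was at least 904-fold higher than the level of 0.0199 CPM that 3 counts over all tumours allow. Without both doubted libraries the bound was 153-fold, with a floor of 0.0232 CPM. The genes MYH2, CKM, MYOT, TTN, PYGM and MYH3, all of striated muscle, had log2 fold changes of −11.71, −11.51, −10.32, −9.09, −8.35 and −8.21, and −4.76, −1.94, −4.25, −1.28, −5.43 and −2.84 without both doubted libraries. Under the patient block MYH2, CKM, MYOT, TTN and MYH3 did not pass, with adjusted p of 0.133, 0.303, 0.0776, 0.319 and 0.163. TTN also lost its call without the skeletal-muscle-rich library alone (adjusted p = 0.241). By limma-voom MYH2, CKM, MYOT, TTN, MYH3 and FABP4 did not pass (adjusted p from 0.154).

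Targets of Wnt/beta-catenin signalling, the pathway that drives crypt renewal, rose in tumours: 13 of 19 measured members were higher and none was lower. Adjusted over the list alone, 16 were higher. The median log2 fold change was 2.24 (camera adjusted p = 3.57e-08, adjusted p = 0.149 with an estimated correlation). AXIN2, a feedback inhibitor of the pathway, rose from 55.7 ± 18.4 to 260 ± 122 CPM (log2 fold change 2.22 ± 0.48 SE, adjusted p = 0.00801). LGR5, a stem cell receptor, rose by a log2 fold change of 3.08 ± 0.85 SE, the crypt transcription factors SOX9, TCF7 and ASCL2 by 2.89 ± 0.59, 3.39 ± 0.62 and 4.41 ± 0.99 SE, and MYC, a driver of cell growth, by 1.43 ± 0.42 SE. Under the patient block AXIN2 and LGR5 had adjusted p of 0.0647 and 0.208. LGR5 and MYC lost their calls in some fits without a single library, with adjusted p up to 0.0613 and 0.0771, and LGR5 by limma-voom (0.19).

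Genes set down beforehand as colorectal tumour markers rose in 12 of 15 cases, with none lower and a median log2 fold change of 5.64 (camera adjusted p = 2.37e-13, adjusted p = 0.0753 with an estimated correlation). Adjusted over the list alone, 13 rose. CEMIP, a hyaluronan-binding protein, had the smallest adjusted p of all genes (0.000845) and rose from 6.74 ± 1.84 to 336 ± 189 CPM. ETV4, an ETS transcription factor, rose by a log2 fold change of 5.76 ± 0.65 SE. REG3A, a secreted lectin, was higher in 3 of 5 pairs, with a log2 fold change of 9.82 ± 2.64 SE, and did not pass with the patient as a block (adjusted p = 0.167) or without some single libraries (adjusted p up to 0.0547), nor by limma-voom (adjusted p = 0.487).

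Cell division genes rose together. Of 16 mitosis genes, 15 were higher, and all 16 when adjusted over the list alone (median log2 fold change 2.58, camera adjusted p = 5.31e-16, adjusted p = 0.149 with an estimated correlation). The mitotic kinase CDK1 rose from 2.81 ± 2.30 to 26.9 ± 7.13 CPM, and TPX2 and UBE2C, which build the spindle and end mitosis, rose by log2 fold changes of 2.87 ± 0.45 SE and 3.57 ± 0.66 SE. The proliferation marker MKI67 stood at 196 ± 231 CPM in adjacent normal colon and 828 ± 390 CPM in tumours without passing (adjusted p = 0.0668), and passed without both doubted libraries (adjusted p = 0.0445), by DESeq2 (0.0134) and by limma-voom (0.0232). Of 16 DNA replication genes, 12 rose, and 14 when adjusted over the list alone (median 1.63, camera adjusted p = 8.85e-09, adjusted p = 0.263 with an estimated correlation). The helicase subunit MCM7 rose by a log2 fold change of 1.52 ± 0.30 SE, GINS1 by 2.35 ± 0.49 SE and the nucleotide reductase RRM2 by 2.4 ± 0.71 SE, RRM2 losing its call without some single libraries (adjusted p up to 0.0717). Ribosome biogenesis genes rose in 11 of 15 cases, and in 14 when adjusted over the list alone (median 1.14, camera adjusted p = 2.32e-09, adjusted p = 0.149 with an estimated correlation). NOP58, a snoRNA-binding protein, rose from 38.5 ± 12.7 to 129 ± 22.9 CPM and DKC1, a pseudouridine synthase, from 48 ± 15 to 151 ± 28 CPM, both in all 5 pairs.

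Extracellular proteases and invasion genes were higher in 6 of 13 cases, and in 10 when adjusted over the list alone (median log2 fold change 2.72, camera adjusted p = 5.49e-06, adjusted p = 0.149 with an estimated correlation). The collagenase MMP1 rose from 1.24 ± 2.16 to 143 ± 191 CPM. Neutrophil chemokines and inflammation genes rose in 6 of 11 cases, and in 7 when adjusted over the list alone (median 3.75, camera adjusted p = 0.00905, adjusted p = 0.507 with an estimated correlation). CCL20, a chemokine for immature dendritic cells, rose from 3.14 ± 2.72 to 41.4 ± 21 CPM. The neutrophil attractants CXCL3, CXCL5 and CXCL8 rose by log2 fold changes of 3.68 ± 0.83, 7.15 ± 2.06 and 6.40 ± 1.82 SE, and had adjusted p of 0.0677, 0.0643 and 0.0943 with the patient as a block. Without tumour replicate 2 the log2 fold change of CXCL8 was 2.61 and the median of the list 1.70. CXCL5 and CXCL8 lost their calls without some single libraries (adjusted p up to 0.0662 and 0.0675). By limma-voom MMP1, CCL20, CXCL5 and CXCL8 did not pass (adjusted p = 0.0606, 0.0646, 0.112 and 0.107). Of 14 glycolysis and hypoxia genes 4 rose and none fell, over all genes and adjusted over the list alone, and the list as a whole did not pass (median 0.48, camera adjusted p = 0.173, and 0.0193 with the patient as a block). That median ran from −0.0321 to 0.879 without single libraries. The glycolytic enzyme PGK1 rose by a log2 fold change of 0.95 ± 0.21 SE and the vessel growth factor VEGFA by 1.56 ± 0.41 SE, with adjusted p of 0.0588 and 0.0520 under the block, and VEGFA had 0.0557 without 1 single library. Of 17 activated fibroblast genes 2 rose, and 0 when adjusted over the list alone, and the list did not pass (median 0.51, camera adjusted p = 0.426, and 0.0108 with the patient as a block). These were the fibrillar and network collagens COL11A1 and COL10A1, with log2 fold changes of 4.15 ± 1.28 SE and 5.56 ± 1.68 SE. Both lost their calls without some single libraries (adjusted p up to 0.0855 and 0.0773), and by limma-voom (0.0694 and 0.126), and COL10A1 also under the block (adjusted p = 0.0958). COL1A1, the main fibrillar collagen, stood at 3454 ± 4386 CPM in adjacent normal colon and 4916 ± 5154 CPM in tumours (adjusted p = 0.737). The skeletal-muscle-rich library held 11139 CPM of it, against 562 to 2662 CPM in the other adjacent normal libraries. Without that library the log2 fold change of COL1A1 was 1.65 (adjusted p = 0.252). The fibroblast list then had a median of 1.17 with 4 genes higher (camera adjusted p = 0.0607). Under the block without both doubted libraries the list passed (camera adjusted p = 0.000149).

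Of 20 absorptive colonocyte genes, 12 fell and none rose, and 18 fell when adjusted over the list alone (median log2 fold change −3.98, camera adjusted p = 5.52e-08, adjusted p = 0.366 with an estimated correlation). Without the skeletal-muscle-rich library, in which these genes were also low, 18 fell over all genes. BEST4 and OTOP2, an anion channel and a proton channel of a rare absorptive cell, fell from 27.4 ± 21.6 to 0.293 ± 0.293 CPM and from 96.2 ± 61.9 to 0.470 ± 0.687 CPM, and did not pass by limma-voom (adjusted p = 0.260 and 0.324). The carbonic anhydrase CA1 stood at 2588 ± 1680 against 125 ± 244 CPM (adjusted p = 0.0752) and the keratin KRT20 at 662 ± 411 against 119 ± 99.7 CPM (adjusted p = 0.121). Without both doubted libraries CA1 and KRT20 passed, with adjusted p of 0.0418 and 0.0218, and by DESeq2 with 0.00432 and 0.0372. None of 13 goblet cell genes passed, over all genes or adjusted over the list alone (median −1.47, camera adjusted p = 0.286), and without the skeletal-muscle-rich library the list passed (camera adjusted p = 0.00329) with 1 gene lower. The mucin MUC2 had a log2 fold change of −1.47 ± 1.27 SE and the mucus protein FCGBP of −2.02 ± 1.11 SE, FCGBP passing without both doubted libraries (adjusted p = 0.0390). Of 7 enteroendocrine genes 2 fell, SCG2 and the hormone SST, by log2 fold changes of −3.58 ± 1.04 SE and −4.46 ± 1.42 SE, and 5 when adjusted over the list alone (median −3.58, camera adjusted p = 0.00411, adjusted p = 0.350 with an estimated correlation). SCG2 and SST had adjusted p of 0.149 and 0.349 with the patient as a block and up to 0.0784 and 0.122 without single libraries, and SST had 0.251 by limma-voom. EPCAM itself stood at 1373 ± 893 CPM in adjacent normal colon and 1941 ± 672 CPM in tumours (adjusted p = 0.702). Its log2 fold change was 0.50, and 0.16 without the skeletal-muscle-rich library.

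Fatty acid oxidation and ketogenesis genes fell in 9 of 13 cases, and in 11 when adjusted over the list alone (median log2 fold change −1.24, camera adjusted p = 5.70e-06, adjusted p = 0.181 with an estimated correlation). ACAA2, a mitochondrial thiolase, fell from 119 ± 62.2 to 36.6 ± 8.45 CPM and ETFDH, an electron transfer enzyme, from 78.5 ± 27.3 to 27.5 ± 10.2 CPM. Xenobiotic and steroid metabolism genes fell in 2 of 15 cases, and in 5 when adjusted over the list alone (median −1.78, camera adjusted p = 0.0118, adjusted p = 0.507 with an estimated correlation). Without the skeletal-muscle-rich library 8 fell, and without adjacent normal replicate 5 the list did not pass (camera adjusted p = 0.0701). The efflux pump ABCG2 and the alcohol dehydrogenase ADH1B fell by log2 fold changes of −5.84 ± 0.89 SE and −6.87 ± 1.48 SE, and ADH1B by −4.21 without the skeletal-muscle-rich library. Of 12 immediate early and heat shock genes 5 fell, and 6 when adjusted over the list alone (median −1.12, camera adjusted p = 0.00493, adjusted p = 0.378 with an estimated correlation). FOS, an AP-1 subunit, fell from 1079 ± 711 to 267 ± 113 CPM and DUSP1, a phosphatase of stress kinases, from 240 ± 125 to 67.3 ± 54.3 CPM. FOS and DUSP1 had adjusted p of 0.0999 and 0.0930 with the patient as a block, and DUSP1 up to 0.0762 without single libraries. The list had a camera adjusted p of 0.0505 under the block without both doubted libraries.

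Genes of the muscle layer, its nerves and fat cells fell in tumours. All 11 smooth muscle genes fell, also when adjusted over the list alone (median log2 fold change −6.52, camera adjusted p = 5.31e-16, adjusted p = 0.149 with an estimated correlation). The myosin MYH11 fell from 43876 ± 44456 to 262 ± 252 CPM, the calcium-binding CASQ2 by a log2 fold change of −8.05 ± 0.86 SE and the filament protein SYNM by −7.05 ± 0.78 SE, each in all 5 pairs. Enteric neuron and glia genes fell in 9 of 10 cases, and in all 10 when adjusted over the list alone (median −4.67, camera adjusted p = 5.52e-08, adjusted p = 0.167 with an estimated correlation). The glial transcription factor gene SOX10 fell by a log2 fold change of −6.26 ± 1.12 SE. All 5 adipocyte genes fell, also when adjusted over the list alone (median −8.60, camera adjusted p = 0.000969, adjusted p = 0.348 with an estimated correlation), and 4 without the skeletal-muscle-rich library. The lipid droplet genes PLIN1 and CIDEC had log2 fold changes of −9.29 ± 1.77 SE and −6.19 ± 1.12 SE, or −5.74 and −4 without that library, and PLIN1 had an adjusted p of 0.106 with the patient as a block and 0.276 by limma-voom. Of 10 endothelial genes 1 fell, also when adjusted over the list alone (median −1.57, camera adjusted p = 0.00905, adjusted p = 0.533 with an estimated correlation). It was the tight junction gene CLDN5 (log2 fold change −2.47 ± 0.66 SE), which had an adjusted p of 0.0534 with the patient as a block. Without the skeletal-muscle-rich library CLDN5 (adjusted p = 0.0539) and the endothelial list (camera adjusted p = 0.133) did not pass. Of 12 genes of bone morphogenetic protein signalling, which opposes Wnt in the crypt, 4 fell, and 5 when adjusted over the list alone (median −1.22, camera adjusted p = 0.0338, adjusted p = 0.206 with an estimated correlation). The ligand BMP3 fell from 12.2 ± 9.20 to 0.389 ± 0.541 CPM, and the secreted antagonist CHRDL1 fell by a log2 fold change of −4.30 ± 1.20 SE, CHRDL1 losing its call with tumours that had a matched normal only (adjusted p = 0.0765). The list did not pass without tumour replicate 7 or without adjacent normal replicate 5 (camera adjusted p up to 0.0848).

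Immune cell genes changed in few cases. Of 13 T and NK cell genes 2 rose, also when adjusted over the list alone (median log2 fold change 0.81, camera adjusted p = 0.0381, adjusted p = 0.533 with an estimated correlation). They were FOXP3 and CTLA4, known as markers of regulatory T cells, which rose from 0.160 ± 0.158 to 1.98 ± 0.744 CPM and from 0.308 ± 0.174 to 1.54 ± 0.619 CPM. CTLA4 had an adjusted p of 0.131 with the patient as a block and up to 0.0672 without single libraries. The killer T cell gene CD8A stood at 4.66 ± 2.66 and 8.20 ± 8.99 CPM (adjusted p = 0.502). The T and NK list did not pass with the patient as a block (camera adjusted p = 0.110) or without 5 of the 12 single libraries (up to 0.137). None of 17 interferon response and antigen presentation genes passed, over all genes or adjusted over the list alone, while the list as a whole did (median 0.83, camera adjusted p = 0.0381, adjusted p = 0.705 with an estimated correlation). It did not pass with the patient as a block (0.0511) or without some single libraries (up to 0.182). Its median ran from 0.231 to 1.32 without single libraries. B2M and HLA-B, parts of class I complexes, had log2 fold changes of −0.11 ± 0.47 SE and 0.49 ± 0.43 SE. None of 11 B cell and plasma cell genes and none of 12 macrophage and monocyte genes passed, over all genes or adjusted over the list alone (medians 0.64 and −0.54, camera adjusted p = 0.387 and 0.332). The antibody joining chain JCHAIN and the B cell receptor gene CD79A had log2 fold changes of −1.68 ± 0.99 SE and −0.35 ± 0.84 SE, and the macrophage genes CD68 and LYZ of 0.13 ± 0.27 SE and 0.72 ± 0.51 SE. The mean of the macrophage list was 0.25, of the other sign than its median. Of 4 hepatocyte genes 1 fell, the iron carrier TF (log2 fold change −3.92 ± 1.18 SE), which lost its call under the block (adjusted p = 0.221) and without single libraries (up to 0.0956) and by limma-voom (0.174). Adjusted over the list alone, 1 hepatocyte gene was higher and 1 lower, and the list did not pass (median −1.95, camera adjusted p = 0.451).

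Regulators of chromatin and DNA methylation, the subject of the wider study, moved in both directions. Smooth muscle genes took 6.49% of the counts in adjacent normal colon and 0.0980% in tumours. Whether such differences in tissue makeup lie behind changes of these regulators was not tested. Of 8 DNA methylation and demethylation enzymes 3 rose and 1 fell, and 3 rose and 2 fell when adjusted over the list alone (median log2 fold change 0.52, camera adjusted p = 0.294). The methyltransferases DNMT1 and DNMT3B rose by log2 fold changes of 1.01 ± 0.33 SE and 1.98 ± 0.52 SE and their partner UHRF1 by 2.21 ± 0.63 SE, while TET1, which oxidises methylated cytosine, fell by 2.05 on the log2 scale. Under the patient block none of DNMT1, DNMT3B, UHRF1 and TET1 passed (adjusted p = 0.150, 0.0891, 0.0620 and 0.17). DNMT1 also lost its call in 10 of 12 fits without a single library (adjusted p up to 0.110), and DNMT3B, UHRF1 and TET1 in 1 to 3 fits (up to 0.05, 0.0675 and 0.0503). By limma-voom DNMT3B and TET1 had 0.0619 and 0.0728. Of 16 genes of Polycomb complexes, which silence genes through histone marks, 7 rose and 3 fell, and 8 rose and 4 fell when adjusted over the list alone (median 0.43, camera adjusted p = 0.156). CBX2 rose by a log2 fold change of 2.73 ± 0.74 SE, CBX6 fell from 12.7 ± 6.94 to 1.73 ± 0.905 CPM, and EZH2, the complex's methyltransferase, rose from 10.6 ± 9.60 to 37.9 ± 15.9 CPM. EZH2 had an adjusted p of 0.0511 with the patient as a block, and EZH2 and CBX2 up to 0.0574 and 0.0630 without single libraries. Of 16 enhancer acetylation and H3K4 methylation factors 2 rose and 1 fell, also when adjusted over the list alone (median −0.06, camera adjusted p = 0.783). They were the acetyltransferase KAT2A (log2 fold change 1.17 ± 0.25 SE), the demethylase KDM1A (0.79 ± 0.21 SE) and the acetyltransferase KAT2B (−1.10 ± 0.35 SE). KAT2A and KDM1A had adjusted p of 0.0537 and 0.0751 with the patient as a block, and KDM1A and KAT2B up to 0.0579 and 0.104 without single libraries. The methyltransferase KMT2D had a log2 fold change of −0.04 ± 0.18 SE.

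Of 12 histone deacetylases 1 rose and 2 fell, also when adjusted over the list alone (median 0.05, mean −0.17, camera adjusted p = 0.744). HDAC9 fell from 35.1 ± 11.1 to 6.19 ± 2.96 CPM and HDAC4 from 133 ± 59.3 to 51.5 ± 6.91 CPM, each in all 5 pairs, HDAC4 with an adjusted p of 0.0594 with the patient as a block. Both belong to class IIa, known from muscle. Of 15 SWI/SNF subunits, parts of a nucleosome remodeller, 2 rose and 1 fell, and 3 rose and 1 fell when adjusted over the list alone (median 0.18, mean −0.04, camera adjusted p = 0.783). SMARCC1 and SMARCD1 rose by log2 fold changes of 0.75 ± 0.22 SE and 0.47 ± 0.14 SE and SMARCD3 fell by 2.17 on the log2 scale. These 3 calls were lost without some single libraries (adjusted p up to 0.0717, 0.0815 and 0.0947), and those of SMARCC1 and SMARCD1 with the patient as a block (0.0797 and 0.164). ARID1A, another subunit, had a log2 fold change of −0.23 ± 0.18 SE. Of 11 intestinal transcription factors 1 fell, and 0 when adjusted over the list alone (median 0.11, mean −0.17, camera adjusted p = 0.666). It was KLF4 (log2 fold change −1.84 ± 0.56 SE), which had an adjusted p of 0.188 with the patient as a block and up to 0.0786 without single libraries, and 0.0914 by limma-voom. CDX2 and HNF4A, which set intestinal identity, had log2 fold changes of 0.74 ± 0.82 SE and 0.35 ± 0.90 SE. Without the skeletal-muscle-rich library these were 0.40 ± 0.39 SE and 0.0061 ± 0.53 SE.

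**Figure D2:**
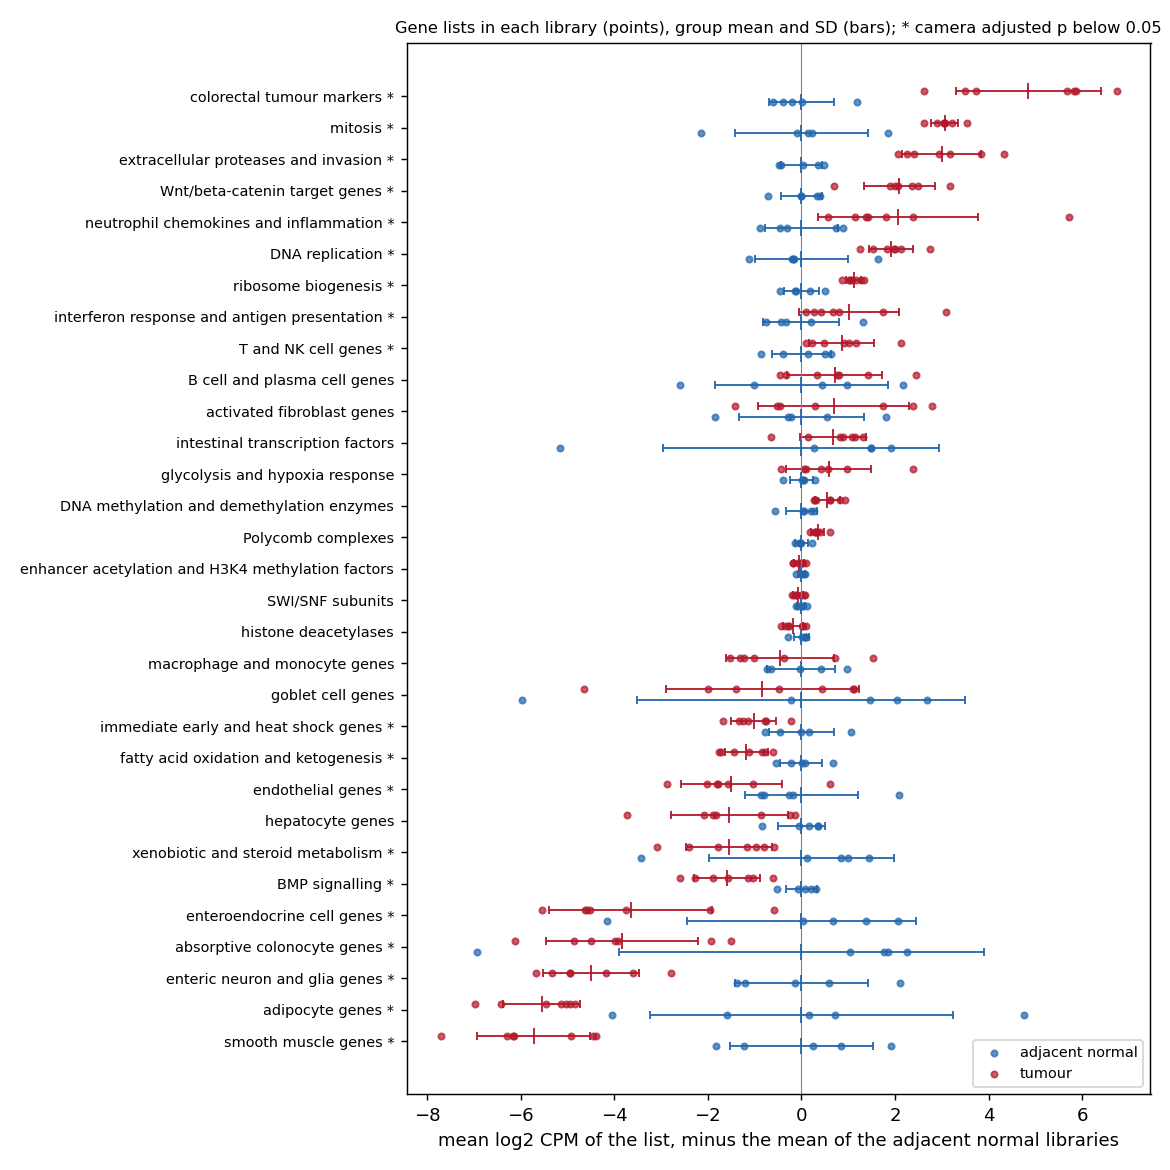
Mean log2 CPM of each of the 31 gene lists in each library, minus the mean of the adjacent normal libraries (horizontal axis), for adjacent normal (blue, n = 5) and tumour (red, n = 7), with bars for the group mean and SD; a star marks lists with a camera adjusted p below 0.05. Colorectal tumour markers lie highest in tumours and smooth muscle genes lowest.

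Over the 31 lists, camera with its preset correlation of 0.01 called 9 higher and 10 lower in tumour, and 12 were not called. With an estimated correlation 0 were called, and the lowest adjusted p was 0.0753. Under the patient block edgeR called fewer members: 7 of the Wnt targets, 5 absorptive colonocyte genes, 4 of fatty acid oxidation, 4 higher among Polycomb genes, 3 neutrophil chemokines, 3 adipocyte genes, 2 of glycolysis and hypoxia, 1 fibroblast gene, 1 T and NK cell gene, and 0 of the enteroendocrine, immediate early and DNA methylation lists. Random splits of the 12 libraries gave as many lists higher in 23 of 100 draws and as many lower in 11 of 100, so the number of lists called was within what regrouping gave, while the gene counts were above it.

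Genes of 8 of 39 chromosome arms shifted as a group. Median log2 fold changes were 0.55 for 13q, 0.56 for 20q, 0.38 for 20p and 0.28 for 6p (camera adjusted p = 0.00103, 0.000284, 0.0413 and 0.0350), and −0.37 for 14q, −0.39 for 17p, −0.41 for 18p and −0.36 for 18q (camera adjusted p = 0.000284, 0.000659, 0.0197 and 0.00103). On 20q, 76.2% of 269 genes had a positive fold change, and on 18q 30.1% of 143 genes. With an estimated correlation 0 arms were called (lowest adjusted p = 0.967), and 63 of 100 random splits shifted at least as many arms. The calls of 20p and 6p were lost without both doubted libraries (adjusted p = 0.0639 and 0.0840) and without some single libraries (up to 0.225 and 0.0703).

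**Figure D3:**
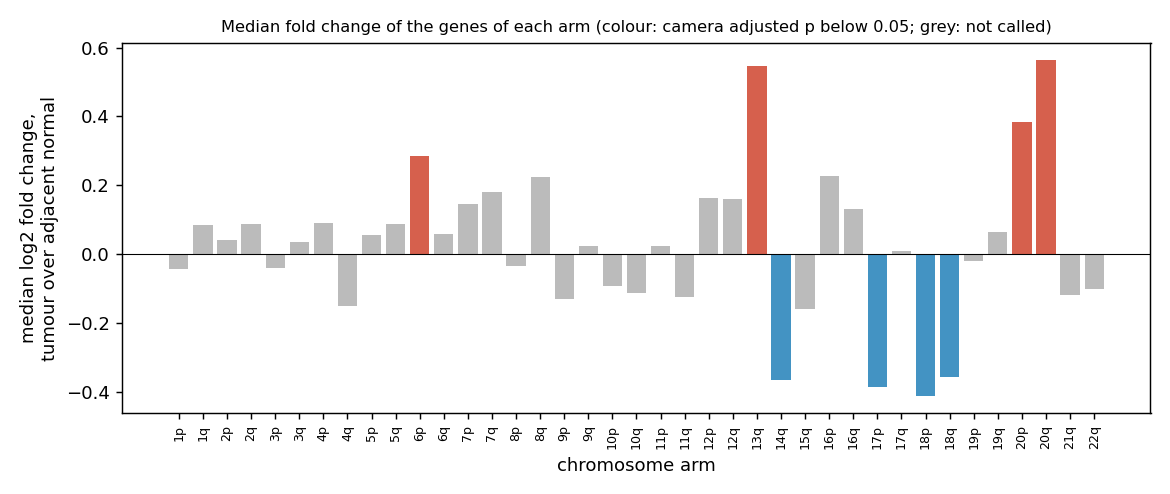
Median log2 fold change of tumour over adjacent normal over the genes of each of the 39 chromosome arms; red and blue bars are arms with a camera adjusted p below 0.05, grey bars are not called. The largest medians are 0.56 on 20q and 0.55 on 13q, and the lowest is −0.41 on 18p.

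The spread of libraries within a group was compared between tumours and adjacent normal colon. The mean distance of a library to the others of its group, as 1 minus Spearman's correlation, was 0.0971 ± 0.0200 in tumours (SD, n = 7) and 0.136 ± 0.0572 in adjacent normal colon (SD, n = 5), a difference of −0.0388 that did not pass a two-sided permutation test of these values (p = 0.0960). The difference ran from −0.0627 to 0.0245 when single libraries were left out, with p below 0.05 without 4 of the 12 (permutation p from 0.0121). It was 0.00978 without both doubted libraries (permutation p = 0.433). The distances were computed once, within the real groups, and share pairs of libraries. Shuffling them as separate values is therefore not exact, and these p-values are a rough guide only.

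The authors' deposited table listed 17301 genes, of which 4775 had an adjusted p below 0.05, 2243 higher and 2532 lower in tumour. Among 14554 genes in both analyses, the authors' deposited table called 4328 and edgeR 3137, with 3118 called by both. All 3118, or 100%, had the same direction, and log2 fold changes correlated across genes with Pearson's r = 0.955, genes not being independent replicates. Of the tested genes 308 were not in the authors' deposited table, 103 of them called here, and these included the skeletal muscle genes ACTA1, MYH7, TTN, NEB, MYH2 and CKM, picked for mention after their values were seen. With the patient as a block 1475 genes were called here and in the authors' deposited table. For KRT17, the authors' deposited table gave a log2 fold change of 2.18 ± 0.65 SE, against 8.67 ± 2.65 SE from edgeR here. Without both doubted libraries edgeR gave 2.64 ± 0.88 SE for KRT17, and leaving out single libraries gave 2.51 to 9.06.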

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

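All tests of explanations in this part were chosen after the results were seen. In 298 checks of a library measure, list mean or named gene within a group, 40 had a library far from the others, where chance gives about 1 in 20 for independent, normally distributed values. Some of these genes were picked for large changes in the same libraries, so the excess lends no support of its own. Of the 40, 18 were the adjacent normal library rich in skeletal muscle genes, 6 the squamous-rich tumour, and 16 other libraries.

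The skeletal-muscle-rich library stood lowest among adjacent normal libraries in mean log2 CPM of absorptive colonocyte genes (−0.59), xenobiotic and steroid metabolism (2.31) and intestinal transcription factors (0.43), and highest for endothelial genes (6.30). It was lowest in log2 CPM of BEST4 (−2.99), OTOP2 (−2.99), MUC2 (5.08), FCGBP (3.90), CDX2 (−2.33), EPCAM (1.54), KRT20 (0.0612), CA1 (2.58), HNF4A (−0.64), SMARCD1 (4.23) and CTLA4 (−3.48), and highest for CKM (12.69), TTN (16.03) and CIDEC (9.07). Skeletal muscle added to colon mucosa is argued against, since 8 pan-epithelial genes had a median ratio of 0.00205 to the other adjacent normal libraries. A swap with a tumour library is argued against, since 0 tumours reached the lowest adjacent normal share of smooth muscle genes. A piece of tissue without colon mucosa and an outside sample under this label cannot be told apart, since both leave all pan-epithelial genes low, and 8 of 8 lay below 0.1 of the mean of the other adjacent normal libraries. The squamous-rich tumour carries the same patient label as this library, and a link between them was not tested. No biological explanation was tested.

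The squamous-rich tumour stood apart in the share of its 10 most abundant genes (25.2%), in log2 CPM of SPRR2D (9.49), KRT17 (14.08) and S100A2 (7.52), and in the low log2 CPM of MUC2 (5.00) and CCL20 (0.70).

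Other single libraries stood apart as follows. Among adjacent normal libraries, 1 detected 15939 genes, and extreme values were 4.70 for the histone deacetylase list, and in log2 CPM −2.29 for MMP7, −2.92 for ATG9B, 6.55 for MCM7, 8.77 for PGK1, 2.38 for MMP1, 7.96 for DNMT1 and −1.36 for CD8A. Among tumours, extreme values were 6.58 for the neutrophil chemokine list, and in log2 CPM −1.98 for SOX10, −0.47 for FOXP3, 12.03 for CXCL8, 5.11 for AXIN2, −0.57 for LGR5 and 6.18 for EZH2. Those of MMP7, ATG9B and SOX10 rest on groups whose other libraries sat at the floor.

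In data outside the comparisons, read pairs that fell in no gene made up 7.09% in tumours against 3.88% in adjacent normal colon (exact two-sided permutation p = 0.0152 with n = 7 and n = 5, adjusted p = 0.0341 over 9 measures).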

How the results depend on the processing

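The alternatives without both doubted libraries were chosen after the result was seen, and the others were fixed before the data were examined. No called gene, list or arm changed sign. Values without a call did in 14 cases over 5 genes (B2M, CD68, CD79A, JCHAIN and KMT2D) and in 12 cases over 5 lists, and the distance difference, without a call, in 2. Over the 110 genes picked by the naming rule, 2385 of 2699 values kept their side of the threshold, 298 lost the call and 16 gained it. Over 31 lists the counts were 667, 38 and 8 of 713, and over 8 arms 165 of 184 were kept and 19 lost. Counts of genes stayed within 1.5 times for all scalings, filters, tools, unstranded counts, robust dispersion and the patient as a random effect. With tumours that had a matched normal only, fewer samples gave 1797 genes, 904 higher and 893 lower, 1548 at least 2-fold, and 1731 shared with the authors' deposited table. With the patient as a block (replicate block), which leaves fewer degrees of freedom, the counts were 1558, 663, 895, 1483 and 1475, and the block turned the lists and named genes given above. Without both doubted libraries and with that block they were 1568, 580, 988 and 1551. An adjusted p of 0.01 left 1064 genes shared with the authors' deposited table. With an estimated correlation, 0 lists were higher, 0 lower and 0 arms shifted. With no low-count filter 5 arms shifted, and the cause was not tested. Without single libraries the genes differing ran from 2080 to 3837, genes higher from 889 to 1944, and the distance difference from −0.0627 to 0.0245, permutation p 0.0121 to 0.240. Without both doubted libraries the calls of KAT2B, SMARCD1, SMARCD3, TF and DNMT1 were also lost. Of the 110 genes, limma-voom ended 32 calls, the random effect 27, the patient block 37, tumours with a matched normal only 19, and the block without both doubted libraries 31, MCM7, ETFDH and FOXP3 among these (adjusted p = 0.0606, 0.0572 and 0.0690). Without a low-count filter 2 ended, and with DESeq2 size factors 1. Depth limits genes near 1 CPM. The simulated comparison, in which a much smaller share of genes differed than was called here, recovered few 2-fold changes.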

Other observations

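Gene groups not fixed beforehand were looked up after the results were seen, as were all tests of explanations in this part. Small nucleolar RNA genes, which guide modification of ribosomal RNA, were higher in tumours in 62 of 116 cases and lower in 1 (median log2 fold change 2.01). The protocols name kits for coding transcripts or mRNA. Whether these counts stem from the small RNAs themselves or from other transcripts at the same places cannot be told. Tumour libraries also held more read pairs in no gene (7.09% against 3.88%) and more ambiguous pairs (1.69% against 1.10%). Replication-dependent histone genes rose in 34 of 58 cases (median 1.96). Chaperonins, which fold new proteins, rose in 8 of 12 cases (median 0.88), nucleoporins in 8 of 17 (0.65), serine and mitochondrial one-carbon enzymes in 4 of 10 (0.85), aminoacyl-tRNA synthetases in 6 of 15 (0.39) and RNA polymerase I and III subunits in 2 of 13 (0.49). All 7 groups passed camera with the preset correlation, with adjusted p up to 0.0219, and none with an estimated one (adjusted p = 0.126 or higher). Without both doubted libraries 61 small nucleolar RNA genes and 32 histone genes were higher. Pan-epithelial colon genes changed in 0 of 8 cases by edgeR (median 0.24, camera adjusted p = 0.326). Skeletal muscle genes were lower in 11 of 13 cases (camera adjusted p = 0.0282, adjusted p = 0.641 with an estimated correlation) and squamous genes higher in 5 of 12 (camera adjusted p = 0.185). Without both doubted libraries 3 of 12 skeletal muscle genes were lower and 1 higher, and 0 of 12 squamous genes passed by edgeR.

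The number of genes that differ was not matched by regrouping. Over 100 splits of the 12 libraries, 1 split, the real one, reached 3240 genes, the highest other giving 1135, and 95 of the others gave 0. Genes higher (1590 against 361), lower (1650 against 774) and at least 2-fold changed (2512 against 1007) were each reached by 1 of 100, the real one. That is the smallest share these draws could give, and they covered 100 of the 792 splits. Chance is thus argued against for these counts, but not excluded. The highest other split kept 6 of the tumours together. The 5 other splits that part all 5 pairs like the real one gave at most 176 genes. For lists and arms chance is not argued against: 23 of 100 splits gave 9 or more lists higher (highest other 14), 11 gave 10 or more lower (highest other 12), and 63 shifted 8 or more arms (highest other 18).

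Smooth muscle and enteric neuron genes fell together in tumours. Scaling is argued against as the cause, since the smaller median of the smooth muscle list over both other scalings was −6.50, and so is the skeletal-muscle-rich library, since the median without it was −6.87. More muscle wall in the adjacent normal pieces and loss of these cells in the tumours cannot be told apart, since both lower the members of both lists, of which 20 of 21 tested were lower.

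Arms often gained in colorectal cancer (7p, 7q, 8q, 13q, 20p, 20q) were set against arms often lost (8p, 17p, 18p, 18q), 1681 against 636 genes. The difference in mean log2 CPM was 0.44 ± 0.32 in tumours (SD, n = 7) and −0.07 ± 0.03 in adjacent normal colon (SD, n = 5) (exact two-sided permutation p = 0.0126). This p lends no support of its own, since the arms were picked after the results were seen and hold 6 of the 8 called arms, without 14q and 6p. GC content and transcript length are argued against, since 99.9% of the difference stayed once their trend was removed, in the fits with and without the replicate block, as are the doubted libraries, without which 103% stayed (exact p = 0.0381). Copy number changes in the tumours stay open, as a hypothesis that DNA was not analysed here to test.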
